A study of Rattus norvegicus with 12 samples.

How the data were processed

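Total RNA from flash-frozen rat dorsal root ganglia was extracted with Trizol and made into libraries with a BGISEQ-500 kit, per the labels' protocols, which also speak of Illumina protocols and do not say whether strand was kept. There were 12 libraries in 3 groups of 4, vehicle, paclitaxel and oxaliplatin, taken with their replicate numbers from the sample titles. Each library had a deposited table with an estimated count and an FPKM value (fragments scaled to transcript length and library total) for each gene. Per the file headers, the estimated counts were expected counts, which need not be whole because reads that match several genes are divided between them. The submitters' processing notes name CASAVA 1.4 and Bowtie2, while the quantification tool, its settings and the genome build were not given in the sources used here. The deposited tables list only genes with an FPKM of at least 0.01, and a gene absent from a table was taken as 0.

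Estimated counts summed to between 17008728 and 17615736 per library, with 17987 to 18215 genes listed in each, 20152 over all libraries. Between 30.3% and 31.5% of the estimated counts were not whole, and the 10 most abundant genes held 3.97% to 4.82% of the counts. The precision of each value is that of 4 libraries per group, and the square root of the common dispersion was 0.159. Genes carry NCBI gene IDs, of which 18549 (92.0%) were found in a RefSeq gene table of assembly GRCr8. That table was used for names only, since the build behind the files is not known, and no coordinates are given. The files held 27 symbols that spreadsheet software had turned into dates and 32 symbols shared by more than 1 ID, and 59 genes were renamed from the table. A gene whose estimated count was not whole in more than 6 libraries is called uncertain, because its reads may be shared with a paralog, pseudogene or overlapping gene.

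Estimated counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3, with the default expression filter, TMM normalisation and a robust quasi-likelihood fit of the 3 group means over all 12 libraries (9 residual degrees of freedom). The filter left 15809 genes, with at least 99.9% of the counts of each library, and set aside 4343. Tests were two-sided, and a gene was called at an adjusted p (Benjamini-Hochberg) under 0.05. The labels give no pairing, so none was used. Counts of 2 libraries of a group were compared by chi-square per gene (summed count of at least 50), which lay between 8.07 and 44.9, so no 2 libraries agreed within sampling noise. Spearman correlations were 0.98 to 0.992 within groups and 0.97 to 0.992 between groups.

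Gene lists and the design were fixed before the data were examined. Of the lists, 47 had at least 4 tested members and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation of 0.01), adjusted over the 47 lists of a comparison. Camera with an estimated correlation and fry stand beside it. A list of genes of the mitochondrial genome had too few members to test. The score of a list in a library is the mean log2 CPM of its tested members minus the mean over the vehicle libraries. The lists hold known members of pathways and markers of cell types that the tissue or its surroundings could hold, and some share genes: 12 of 30 axon injury genes and 7 of 22 macrophage markers are also in another list.

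Genes are named by a rule fixed in advance. It takes, for each comparison, the 10 genes with the smallest p in each direction among those called with a mean log2 CPM of at least 1, a proper symbol and no overlap between groups, and the 2 with the largest fold each way. It adds up to 4 members of each list described, the called ones by smallest p or otherwise the 2 with the smallest p, and 9 genes chosen for pain and injury: Atf3, Gal, Calca, Trpv1, Trpa1, Scn9a, Scn10a, Cdkn1a and Ccl2. Which list members the text names within that rule was chosen after the values were seen. Some genes that the rule or a count would name are not reported here.

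The scripts were tested on counts simulated from the real means. For the paclitaxel comparison 76.8% of genes changed 2-fold and 97.9% of those changed 4-fold were called in the right direction, in a run on 15581 genes, and 3.2% of the genes called had not been changed. For the oxaliplatin comparison, also run on 15581 genes, 77.3% and 97.9% were called in the right direction, and 2.9% of the genes called had not been changed. In the paclitaxel comparison the list made to change was called, and in both comparisons 0 unchanged lists were, of 47 run. Each gene was drawn independently, so this cannot show how often camera calls lists whose members move together. When the real libraries of each comparison were divided otherwise, camera called up to 30 lists for paclitaxel, 27 for oxaliplatin and 33 between the drugs.

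Alternatives fixed in advance were DESeq2 1.42.0, limma voom with quality weights, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) from the deposited FPKM values, RLE and upper-quartile normalisation, other filters, a fold of at least 2, only the 2 groups compared, the replicate number as a block, and each library left out in turn. The erythroid score as a covariate, a correction of each library for its trend with gene length, and a fit without genes that share reads were added after the data were seen. GC content was not tested, since no genome sequence was used here. Drug effects were compared beside 20 simulations of unchanged groups that shared simulated vehicle libraries.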

Results

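RNA from dorsal root ganglia of rats, the clusters of sensory neuron cell bodies beside the spinal cord, was sequenced in 12 libraries. There were 4 libraries from rats given vehicle, 4 from rats given paclitaxel at 2.0 mg/kg, a drug that stabilises microtubules, and 4 from rats given oxaliplatin at 2.4 mg/kg, a platinum compound that damages DNA. Each drug was injected into the peritoneal cavity to produce painful peripheral neuropathy, and the comparisons ask how the ganglion transcriptome differed from vehicle after each drug and between the drugs. Paclitaxel was dissolved in DMSO and diluted in saline and oxaliplatin in glucose solution, but there was 1 vehicle group, so a difference from vehicle includes any effect of a solvent that group did not receive. Estimated counts summed to between 17008728 and 17615736 per library, and 15809 of the 20152 genes listed were tested. The labels do not say whether replicates came from separate animals, nor at what hour tissue was taken, so p-values measure the spread between these samples, which may be technical. Expression is given below as mean CPM, counts scaled to the size of each library, ± SD (n = 4 libraries per group), and differences as log2 fold changes ± standard error. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from camera in limma unless another test is named.

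After paclitaxel, 3 genes known from injured sensory neurons rose together. Ecel1 (gene ID 60417), a membrane endopeptidase induced in injured neurons, rose 11.0-fold, from 2.98 ± 1.02 to 32.8 ± 2.96 CPM (log2 fold change 3.45 ± 0.28, adjusted p = 0.000152, edgeR). Gal (29141), the neuropeptide galanin, rose 3.81-fold, from 8.39 ± 2.14 to 32.0 ± 6.01 CPM (1.93 ± 0.23, adjusted p = 0.0024). Atf3 (25389), a stress-induced transcription factor, rose 2.31-fold, from 10.01 ± 1.87 to 23.1 ± 3.27 CPM (1.21 ± 0.15, adjusted p = 0.00323). Genes expressed by macrophages fell. Adgre1 (316137), a surface receptor of macrophages, went from 17.7 ± 3.62 to 6.73 ± 1.72 CPM (-1.39 ± 0.22, adjusted p = 0.0194). Spi1 (366126), the myeloid transcription factor PU.1, went from 11.8 ± 1.60 to 6.91 ± 0.361 CPM (-0.77 ± 0.12, adjusted p = 0.0132). In all, 19 genes passed the test, 13 higher and 6 lower.

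Of the other genes named by the rule fixed in advance, Fam150b, a ligand of the ALK receptor family, rose 7.10-fold (2.83 ± 0.36, adjusted p = 0.00753, edgeR) and Azin2, an antizyme inhibitor, 1.41-fold (0.50 ± 0.09, adjusted p = 0.0367). Igf1, insulin-like growth factor 1, fell from 73.8 ± 14.9 to 31.2 ± 6.49 CPM (-1.24 ± 0.19, adjusted p = 0.0132). Tifab fell by 1.29 ± 0.22 on the log2 scale and Blnk, a B-cell receptor adaptor also found in macrophages, by 1.30 ± 0.22, with adjusted p-values of 0.0349 and 0.0367. Atf3 is uncertain, because its estimated count was not whole in 11 of 12 libraries, as happens when reads are shared with another gene.

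Among gene lists fixed before the data were examined, the axon injury response rose after paclitaxel (median log2 fold change 0.32 over 26 tested members, camera adjusted p = 3.72e-07). Ecel1, Gal and Atf3 were its 3 members called over all genes, and adjusted over the list alone 13 members rose and 2 fell. The adjusted p was 0.11 with an estimated correlation and 0.0017 by fry, which asks whether the members move one way on balance. Neuronal markers moved with it: all 16 were higher (median 0.27, adjusted p = 6.7e-06), with 0 called over all genes and 9 adjusted over the list alone. Tubb3, a neuronal tubulin, had 0.39 ± 0.11 without passing (adjusted p = 0.203). Tubulins and microtubule proteins (median 0.18), synaptic vesicle and presynaptic genes (0.18), calcium and HCN channels (0.24), axonal transport motors (0.11), potassium channels (0.13), and neuropeptides and neurotrophic factors (0.14) also rose, with camera adjusted p-values of 5.66e-06, 0.000126, 0.000785, 0.00954, 0.0311 and 0.0118. Their adjusted p-values with an estimated correlation, in that order, were 0.413, 0.465, 0.465, 0.473, 0.564 and 0.413, and that of the neuronal markers was 0.438. The score of a list, the mean log2 CPM of its members minus the vehicle mean, set paclitaxel 4 apart. It was 0.04 there for neuronal markers, 0.01 for tubulins, -0.04 for synaptic vesicle genes, -0.02 for calcium and HCN channels, -0.02 for motors and -0.09 for potassium channels, each within the range of the vehicle libraries, and between 0.12 and 0.39 in paclitaxel 1, 2 and 3. For the neuropeptide list only paclitaxel 1 (0.35) lay above all vehicle libraries (-0.18 to 0.23). Camera did not call the markers of single neuron classes after paclitaxel: peptidergic and non-peptidergic nociceptors, which sense pain, and large myelinated neurons. Their scores in paclitaxel 1, 2 and 3 were 0.07 to 0.13, -0.021 to 0.065 and 0.08 to 0.26, where neuronal markers had 0.21 to 0.39. Sv2a, a synaptic vesicle protein, had 0.39 ± 0.11 and Kcnk3, a leak potassium channel, 0.97 ± 0.19, neither past the threshold (adjusted p = 0.203 and 0.0975, edgeR).

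Lists of immune and blood cells fell after paclitaxel. All 22 macrophage markers were lower (median -0.84, camera adjusted p = 5.19e-15), 1 of them, Adgre1, called over all genes and 20 adjusted over the list alone (adjusted p = 0.413 with an estimated correlation and 0.0429 by fry). All 17 neutrophil markers were lower (median -1.47, adjusted p = 6.67e-09), 12 of them adjusted over the list alone. Ctsg, a neutrophil granule protease, had -2.91 ± 0.73 (adjusted p = 0.19). Erythroid markers (median -0.85, adjusted p = 1.69e-05) and markers of B and plasma cells (median -0.85, adjusted p = 0.00809) fell beside them. With an estimated correlation the adjusted p-values of these 3 lists were 0.413, 0.465 and 0.541. Complement (median -0.46), MHC class II presentation (-0.46), cytokines and chemokines (-0.57) and the Toll-like receptor pathway (-0.24) fell with camera adjusted p-values of 0.000126, 0.000782, 0.000126 and 4.01e-05, which became 0.438, 0.465, 0.416 and 0.413 with an estimated correlation. The MHC class II scores of paclitaxel 2 and 4 (0.13 and -0.11) were within the vehicle range (-0.45 to 0.34), and those of paclitaxel 1 and 3 (-0.81 and -0.63) below it. Itgam, an integrin of myeloid cells, had -0.89 ± 0.23 and Tlr7, a receptor for single-stranded RNA, -1.22 ± 0.27, and neither passed (adjusted p = 0.198 and 0.137, edgeR).

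Fibroblast and matrix markers fell after paclitaxel as well (median -0.40, camera adjusted p = 2.17e-07), with 0 called over all genes and 9 adjusted over the list alone. So did markers of satellite glia (-0.25, 0.0166), endothelium (-0.17, 0.0157), and bone and cartilage (-0.42, 0.00137). Their adjusted p-values with an estimated correlation were 0.413, 0.541, 0.541 and 0.11. Sfrp4, a secreted Wnt antagonist, had -1.55 ± 0.28 and Col14a1, a collagen, -0.52 ± 0.12, without passing (adjusted p = 0.0671 and 0.144, edgeR). Of 74 cytosolic ribosomal protein genes 73 were lower (median -0.25, adjusted p = 3.36e-07, and adjusted p = 0.564 with an estimated correlation), with 0 called over all genes or adjusted over the list alone, and Rpl7 had -0.46 ± 0.18 (adjusted p = 0.252). Scores of the ribosomal and satellite glial lists were between -0.42 and -0.27 in paclitaxel 1, 2 and 3, while in paclitaxel 4 they were 0.0009 and 0.05, within the vehicle ranges of -0.22 to 0.34 and -0.17 to 0.17. The endothelial scores of paclitaxel 2, 3 and 4 (-0.25, -0.26 and -0.19) were within the vehicle range as well (-0.30 to 0.33). Erythroid and macrophage markers were lower, and neuronal markers higher, beside each of these lists.

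Ecel1, Gal, Atf3 and Fam150b kept their calls whichever library was left out, while Adgre1, Tifab, Blnk and Azin2 each missed the threshold without vehicle 1, 2 or 3 or paclitaxel 1, 2 or 3 (adjusted p between 0.0518 and 0.156, edgeR). Spi1 lost its call without vehicle 1, 2 or 3 or paclitaxel 1 or 3 (0.0519 to 0.0769), Igf1 without vehicle 3 or paclitaxel 1, 2 or 3 (0.0549 to 0.079), and Azin2 and Blnk also without vehicle 4 (0.0833 and 0.0508). The test called 1631 genes without paclitaxel 4 (921 higher and 710 lower), all 19 among them. It called 11 without vehicle 1, 12 without paclitaxel 2 and 10 without paclitaxel 3. With the erythroid score of each library as a covariate, a score that did not overlap between the groups, it called 7. Lower genes called by edgeR went from 6 to 0 without paclitaxel 1 or 3 and with that covariate, to 1 without vehicle 1 or 3 and to 2 without paclitaxel 2, where 1393, 1749, 880, 1961, 2208 and 1916 genes of either direction had an unadjusted p under 0.05. Higher genes numbered 10 to 13 without any 1 library other than paclitaxel 4. The endothelial list was not called without vehicle 1 or 3 (medians -0.0728 and -0.0614, camera adjusted p = 0.0897 and 0.255), nor satellite glia without vehicle 2 or paclitaxel 2 (adjusted p = 0.0822 and 0.0756). Potassium channels were not called without vehicle 2 or paclitaxel 2 or 3 (0.136, 0.0733 and 0.128), nor the neuropeptide and B-cell lists without paclitaxel 4 (0.053 and 0.0943). DESeq2 called 120 genes higher and 118 lower, and limma voom with quality weights 1233 and 1038. Limma called 12 and 9 on log2(FPKM + 1) and 11 and 8 on log2(FPKM + 0.1).

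**Figure D1:**
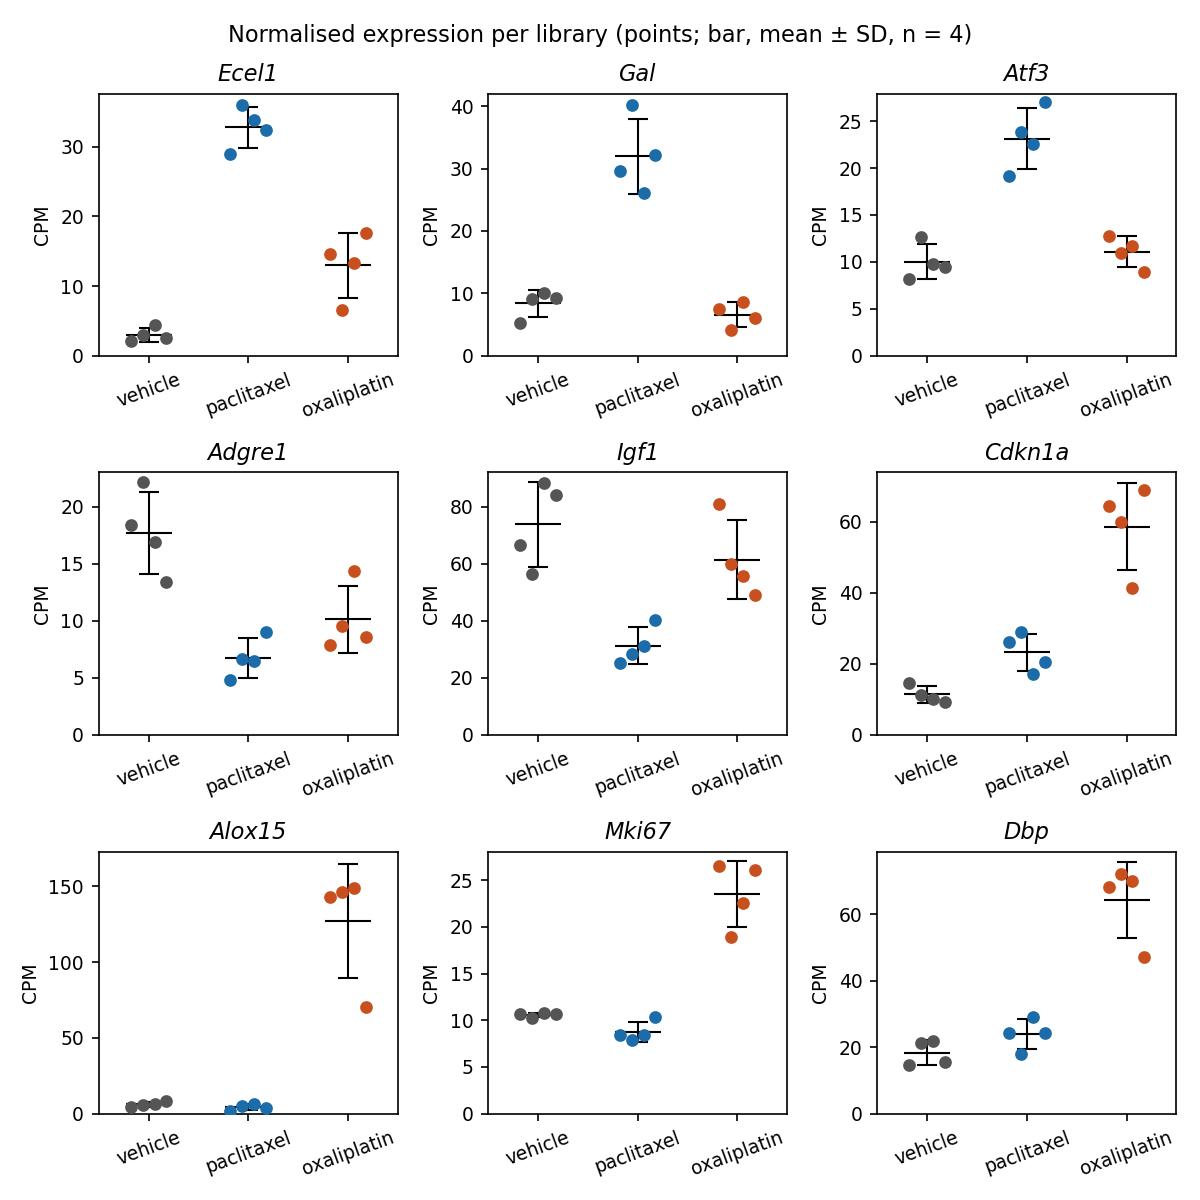
Normalised expression (CPM, vertical axis from 0) of 9 genes in each library of the vehicle, paclitaxel and oxaliplatin groups (points), with the mean ± SD of 4 libraries (bars). Gal reached 26.1 CPM or more in every paclitaxel library and at most 10.1 CPM in any vehicle or oxaliplatin library, and Alox15 was at 70.5 CPM in oxaliplatin 4 and at 143 to 149 CPM in the other oxaliplatin libraries.

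After oxaliplatin, genes of the p53 response, of cell division and of the circadian clock were among those that rose, and tests of their lists are given below. Cdkn1a (gene ID 114851), the cell cycle inhibitor p21 and a p53 target, rose 5.17-fold, from 11.3 ± 2.38 to 58.7 ± 12.1 CPM (log2 fold change 2.37 ± 0.20, adjusted p = 0.000229, edgeR). Alox15 (81639), a lipoxygenase that oxidises arachidonic acid, rose 20.7-fold, from 6.12 ± 1.66 to 127 ± 37.8 CPM (4.37 ± 0.34, adjusted p = 0.000265). Mki67 (291234), the proliferation marker Ki-67, rose 2.22-fold, from 10.6 ± 0.207 to 23.6 ± 3.55 CPM (1.15 ± 0.12, adjusted p = 0.000385). Dbp (24309), a clock-controlled transcription factor, rose 3.51-fold, from 18.3 ± 3.76 to 64.3 ± 11.5 CPM (1.81 ± 0.18, adjusted p = 0.000355). In all, 278 genes passed the test, 166 higher and 112 lower.

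The cell cycle list rose as a whole after oxaliplatin: all 40 members were higher (median 0.80, camera adjusted p = 1.6e-28), 20 of them called over all genes and 31 adjusted over the list alone. The adjusted p was 0.0213 with an estimated correlation. Top2a, topoisomerase II alpha, rose by a log2 fold change of 1.27 ± 0.15, Ccnb2, cyclin B2, by 1.45 ± 0.16, and Mcm5, a replication helicase subunit, by 1.24 ± 0.15 (adjusted p = 0.000891, 0.000608 and 0.0014, edgeR). Of 28 p53 target genes 7 rose and 1 fell over all genes, and 12 rose and 1 fell adjusted over the list alone (median 0.23, camera adjusted p = 0.000122, and adjusted p = 0.0493 with an estimated correlation). Ephx1, a detoxifying epoxide hydrolase, rose from 41.9 ± 3.71 to 80.4 ± 7.33 CPM (0.94 ± 0.09, adjusted p = 0.000355). Ckap2 (1.81 ± 0.21) and Gtse1 (1.47 ± 0.24) also rose (adjusted p = 0.000891 and 0.00959), and as background both encode proteins of dividing cells as well. Gadd45a, a stress gene on this list, was the member that fell (-0.41 ± 0.10, adjusted p = 0.049). Markers of erythroid cells (median 1.28), B and plasma cells (1.25) and adipocytes (1.38) were higher in the same comparison. Mki67, Ccnb2 and Ephx1 are uncertain, since their estimated counts were not whole in 12, 7 and 10 libraries.

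Of 19 circadian clock genes 8 rose and 1 fell after oxaliplatin, and 9 rose and 1 fell adjusted over the list alone (median 0.26, camera adjusted p = 0.000167, adjusted p = 0.119 with an estimated correlation, fry 0.000322). Nr1d1, the repressor REV-ERB alpha, rose 3.92-fold (1.97 ± 0.21, adjusted p = 0.000578, edgeR), Per3 2.04-fold (1.03 ± 0.12, adjusted p = 0.000891) and Tef by 0.53 ± 0.07 (adjusted p = 0.00369). Nr1d1 is uncertain, with an estimated count that was not whole in 12 libraries. Erythroid (median 1.28), B and plasma cell (1.25) and adipocyte (1.38) markers were higher beside the clock list too. Nap1l2, a histone chaperone of neurons, fell from 95.2 ± 7.84 to 47.7 ± 5.04 CPM (-0.99 ± 0.10, adjusted p = 0.000385), and its relative Nap1l5 also fell (-0.47 ± 0.08, adjusted p = 0.0094). Fabp3, a fatty acid binding protein, had -0.85 ± 0.12, Atl1, an endoplasmic reticulum GTPase, -0.47 ± 0.07, and Hebp2 -0.50 ± 0.07, all called (adjusted p = 0.00377, 0.00458 and 0.00323). Ifi27l2b (-0.55), Ccdc126 (-0.63), Mrap2 (-0.51), Nkiras1 (-0.57), Smim18 (-1.21) and Ankrd24 (-1.10, reads shared in 12 libraries) were called lower too, and Ifrd1 (1.11), Thrsp (2.85), a lipogenic gene, and the drug efflux transporter gene Abcb1b (3.25, reads shared in 12 libraries) higher.

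Several neuronal lists fell after oxaliplatin. Beside them markers of erythroid cells (median 1.28), B and plasma cells (1.25), adipocytes (1.38), fibroblasts and matrix (0.32) and endothelium (0.30) were higher. Of 20 markers of non-peptidergic nociceptors, a class of small pain-sensing neurons, 17 were lower (median -0.21, camera adjusted p = 7.29e-05), 1 called over all genes and 5 adjusted over the list alone, and the adjusted p was 0.0229 with an estimated correlation. P2rx3, an ATP-gated channel of these neurons, fell (-0.33 ± 0.07, adjusted p = 0.0413, edgeR). Markers of large myelinated neurons (median -0.17), all neurons (-0.15), potassium channels (-0.17), axonal transport motors (-0.12), synaptic vesicle genes (-0.12), tubulins (-0.11) and inhibitory receptors (-0.16) fell with camera adjusted p-values of 0.00131, 0.00291, 8.7e-05, 0.000417, 0.00182, 0.00554 and 0.00554, each losing the call with an estimated correlation (adjusted p = 0.411, 0.529, 0.411, 0.411, 0.529, 0.529 and 0.411). In oxaliplatin 4 the scores of large myelinated neurons (-0.05), all neurons (0.06), potassium channels (0.03), motors (0.02), synaptic vesicle genes (0.06) and tubulins (0.02) were within the vehicle range, as was that of tubulins in oxaliplatin 1 (-0.04). The neurofilament genes Nefl (-0.67 ± 0.14) and Nefm (-0.63 ± 0.15), the sodium channel gene Scn1a (-0.54 ± 0.13) and the potassium channel genes Kcnv1 (-0.52 ± 0.10) and Kcnip1 (-0.35 ± 0.07) fell. Kcnk3 (1.05 ± 0.19), Tubb6 (0.62 ± 0.12) and the mechanically gated channel gene Piezo1 (0.66 ± 0.14) rose, and the adjusted p-values of these 8 genes lay between 0.0196 and 0.049. Scn1a, Tubb6 and Piezo1 are uncertain because of shared reads. The axon injury list was not called (median -0.13, adjusted p = 0.169): Ecel1 (2.12 ± 0.28) and Csf1 (0.51 ± 0.11) rose and Plaur (-0.69 ± 0.12) and Gadd45a fell.

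Genes of oxidative phosphorylation, cholesterol synthesis and heat shock proteins fell as lists after oxaliplatin. Nuclear genes of oxidative phosphorylation were lower for 69 of 74 members (median -0.17, camera adjusted p = 1.09e-09, with an estimated correlation adjusted p = 0.411), 2 of them, Uqcrfs1 (-0.31 ± 0.06) and Ndufs1 (-0.36 ± 0.08), called over all genes and 2 adjusted over the list alone. Its score was -0.03, -0.08, -0.22 and -0.38 in oxaliplatin 1 to 4 and between -0.08 and 0.16 in vehicle. Cholesterol synthesis genes were lower for 24 of 25 (median -0.27, adjusted p = 3.08e-08), 2 called over all genes and 10 adjusted over the list alone, among them Acat2 (-0.38 ± 0.08, reads shared in 12 libraries) and Sqle (-0.34 ± 0.08). Heat shock protein genes fell (median -0.24, adjusted p = 1.32e-05), with Dnajb4 (-0.35 ± 0.08) and Hsph1 (-0.45 ± 0.10) called and 1 higher and 9 lower adjusted over the list alone. For cholesterol synthesis and heat shock the adjusted p-values were 0.262 and 0.285 with an estimated correlation, and 0.0163 and 0.0211 by fry. Erythroid, B-cell and adipocyte markers were higher, and neuronal markers lower, beside each of these lists.

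Markers of erythroid cells, adipocytes, and B and plasma cells rose after oxaliplatin. Of 17 erythroid markers 16 were higher (median 1.28, camera adjusted p = 2.4e-06), with Kel, a red cell surface protein, called higher (2.22 ± 0.37) and Tfrc, the transferrin receptor, called lower (-0.58 ± 0.11), and 13 higher and 1 lower adjusted over the list alone. Of 13 adipocyte markers 3 rose over all genes, Fabp4 (1.96 ± 0.40), Cidec (2.15 ± 0.47) and Adipoq (2.43 ± 0.55), and 8 adjusted over the list alone (median 1.38, adjusted p = 2.7e-05). Markers of B and plasma cells (median 1.25, adjusted p = 0.000167) had 0 called over all genes and 10 adjusted over the list alone, with Cd79a at 1.77 ± 0.47 (adjusted p = 0.0869, edgeR). Fibroblast and matrix markers (median 0.32, 8.7e-05), which included Fn1 (0.70 ± 0.15), Col6a1 (0.58 ± 0.13) and Col6a2 (0.58 ± 0.13) as called members, rose, as did endothelium (0.30, 0.000299), mural cells (0.24, 0.00101), myelinating Schwann cells (0.14, 0.0351), immediate early genes (0.28, 0.000241) and the interferon response (0.28, 0.00474). Neutrophil markers fell (-0.41, 0.00933). With an estimated correlation the adjusted p-values were 0.411, 0.37, 0.411, 0.411, 0.411, 0.437, 0.685, 0.411, 0.64 and 0.636, in the order given. Markers of skeletal muscle (median 0.10), spinal cord (-0.05), and bone and cartilage (-0.09) were not called (adjusted p = 0.273, 0.353 and 0.594). Isg20, an interferon-induced exonuclease, rose (1.36 ± 0.25, adjusted p = 0.0191). The erythroid score was 1.56 and 1.55 in oxaliplatin 1 and 3 and 0.45 and 0.36 in oxaliplatin 2 and 4, and the B and plasma cell score 1.72 and 1.71 in oxaliplatin 1 and 3, 0.39 in oxaliplatin 4 and -0.14, within the vehicle range of -0.20 to 0.17, in oxaliplatin 2. Adipocyte scores were between 0.69 and 1.75 in the oxaliplatin libraries and at most 0.37 in vehicle. Also within the vehicle range were the fibroblast scores of oxaliplatin 3 and 4, the endothelial of 2 and 4, the mural of 4, the immediate early of 3 and 4, the myelinating Schwann of 1, 3 and 4 and the neutrophil of 1 and 3, and the interferon score of oxaliplatin 1 (-0.11) was not above it.

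Cdkn1a, Alox15, Mki67, Dbp, Top2a, Ccnb2, Mcm5, Ephx1, Nr1d1, Per3 and Nap1l2 kept their calls whichever library was left out, and each such fit kept between 28 and 50 of the 63 named genes called. The count was 98, 84 or 49 genes without vehicle 1, 2 or 4, and 92, 155, 105 or 168 without oxaliplatin 1, 2, 3 or 4. It was 161 without the paclitaxel libraries in the fit and 21 with the erythroid score as a covariate. The myelinating Schwann cell list was not called without vehicle 3 or 4 or oxaliplatin 2 (adjusted p = 0.67, 0.0664 and 0.726), nor neutrophils without vehicle 3 or oxaliplatin 2 or 4 (0.0984, 0.357 and 0.0568). Inhibitory receptors were not called without oxaliplatin 1 (0.0581), tubulins without oxaliplatin 3 (0.112) or the interferon response without oxaliplatin 4 (0.237). Without oxaliplatin 2 the median was 0.0005 for myelinating Schwann cells and -0.137 for neutrophils, and without oxaliplatin 4 it was 0.0705 for the interferon response. DESeq2 called 436 genes higher and 468 lower, and edgeR after correction for gene length 205 and 213. Limma called 229 and 73 on log2(FPKM + 1) and 165 and 59 on log2(FPKM + 0.1).

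**Figure D2:**
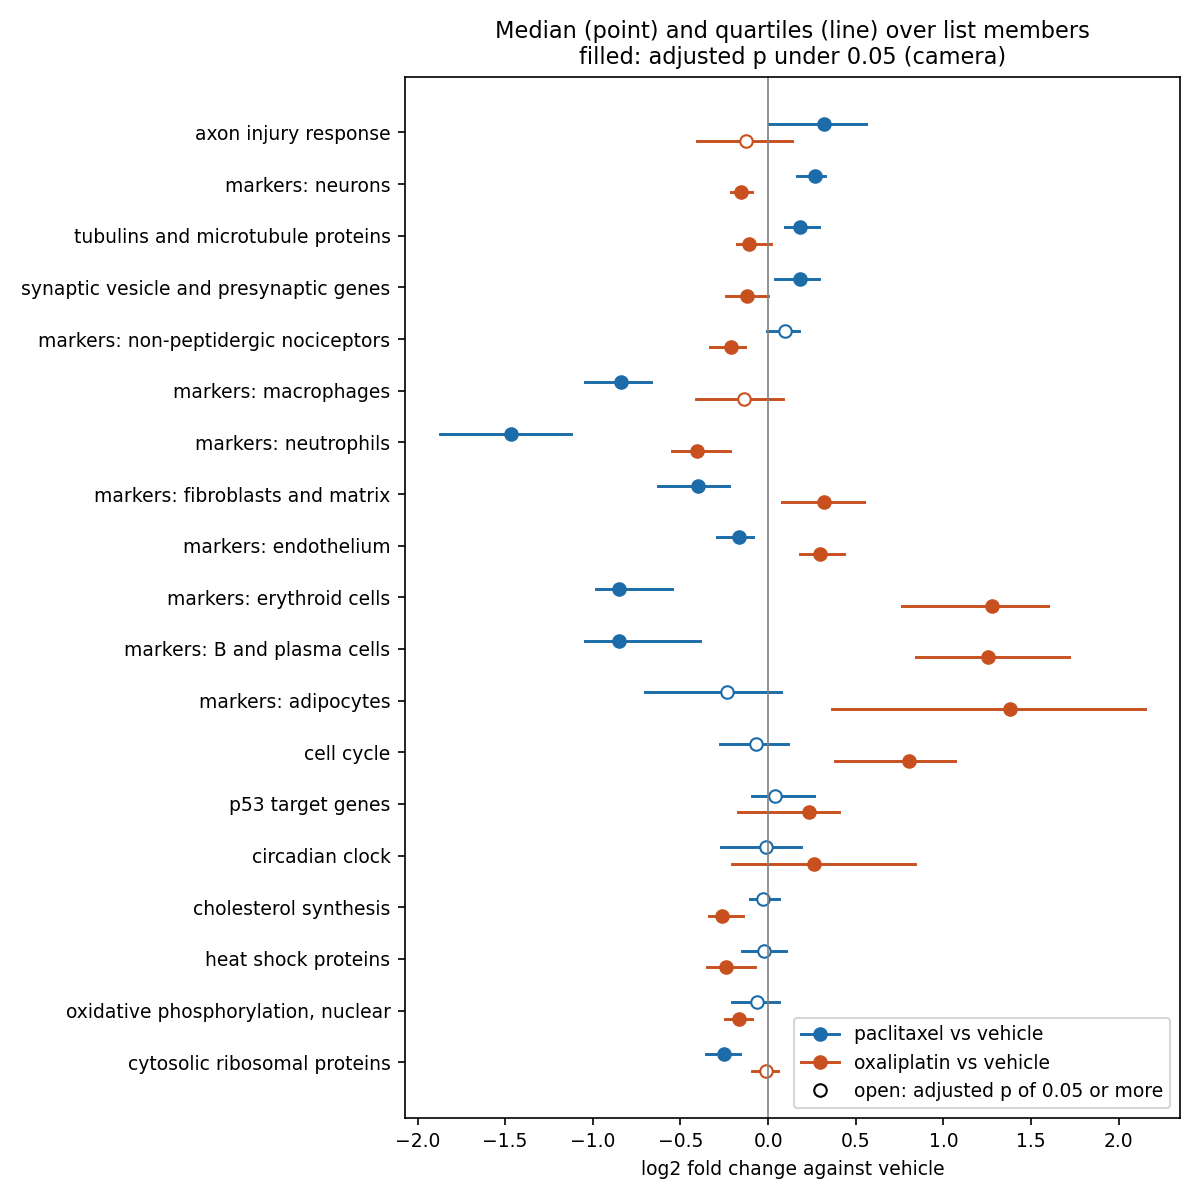
Median log2 fold change (points) and quartiles (lines) over the members of 19 gene lists, for paclitaxel against vehicle and oxaliplatin against vehicle. Filled points passed camera at an adjusted p of 0.05. The macrophage median was -0.84 after paclitaxel and -0.14 after oxaliplatin, and the cell cycle median -0.07 and 0.80.

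With oxaliplatin, compared directly with paclitaxel, genes of cell division and macrophages were among those higher and genes of injury and neurons among those lower. Of the lists of these groups, given below, only those of the cell cycle and of non-peptidergic nociceptors were called by camera with an estimated correlation. Mki67 was higher 2.69-fold (log2 fold change 1.43 ± 0.12, adjusted p = 0.000119, edgeR), Alox15 29.7-fold (4.89 ± 0.36, adjusted p = 0.000119), Cd68, a lysosomal protein of macrophages, 2.37-fold (1.24 ± 0.14, adjusted p = 0.000639) and Cdkn1a 2.53-fold (1.34 ± 0.19, adjusted p = 0.00257). Gal was lower by 2.28 ± 0.23 on the log2 scale (adjusted p = 0.000298), Atf3 by 1.06 ± 0.15 (0.00235) and Ecel1 by 1.33 ± 0.24 (0.00783). Ecel1 was still higher with oxaliplatin than with vehicle, as given above. In all, 1788 genes passed the test, 1044 higher with oxaliplatin and 744 lower.

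Over the cell cycle list 27 of 40 members were called higher with oxaliplatin than with paclitaxel and 34 adjusted over the list alone (median 0.95, camera adjusted p = 1.43e-20, and 0.0324 with an estimated correlation). They included Top2a (1.58 ± 0.15) and Cenpf (1.85 ± 0.21), a kinetochore protein gene. Also higher were Arhgap11a (1.25 ± 0.13), the p53 target Rbm38 (1.92 ± 0.19), the matrix protease gene Mmp2 (1.11 ± 0.12), Spi1 (1.01 ± 0.12), Per3 (1.04 ± 0.12) and Thrsp (3.74 ± 0.58). Lower were Gadd45a (-0.78 ± 0.10), the tubulin-binding stathmin gene Stmn4 (-0.77 ± 0.10), Plaur (-0.83 ± 0.12), Nap1l2 (-0.72 ± 0.10), Mrap2 (-0.56 ± 0.08), Rbm11 (-0.56 ± 0.08), Zwint (-0.49 ± 0.07) and Srxn1 (-0.57 ± 0.08, reads shared in 12 libraries). All these genes had adjusted p-values between 0.000266 and 0.00515 (edgeR). Of 20 non-peptidergic nociceptor markers 8 were called lower and 1 higher (median -0.28, camera adjusted p = 7.17e-05, and 0.0324 with an estimated correlation), among them Sst, somatostatin (-0.94 ± 0.16), and Il31ra, an itch receptor subunit (-0.60 ± 0.12, reads shared in 12 libraries). Adjusted over the list alone, 11 were lower and 1 higher. Beside the cell cycle and nociceptor lists, erythroid, B and plasma cell, adipocyte and fibroblast markers were higher and neuronal markers lower, as given below.

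Macrophage markers were all 22 higher with oxaliplatin than with paclitaxel (median 0.66, camera adjusted p = 2.65e-08), 8 called over all genes, among them Cd14 (0.77 ± 0.18, reads shared in 12 libraries) and Ptprc, CD45 (1.65 ± 0.39), and 17 adjusted over the list alone. The macrophage scores of the oxaliplatin libraries (-0.29 to 0.11) lay within the vehicle range (-0.31 to 0.26), and those of the paclitaxel libraries (-1.49 to -0.61) below it. Fibroblast and matrix markers had 14 of 24 called higher and 20 adjusted over the list alone (median 0.77, adjusted p = 1.5e-11), among them Col5a1 (0.74 ± 0.10) and Col3a1 (0.81 ± 0.13). Complement had 12 of 25 higher and 2 lower (median 0.58, 2.47e-05), among them C1s (1.10 ± 0.19). Neuronal markers had 7 of 16 called lower and 14 adjusted over the list alone (median -0.38, 2.65e-08), with Tubb3 (-0.58 ± 0.11, reads shared in 12 libraries) and Stmn2 (-0.45 ± 0.09). Axon injury genes had 11 lower and 1 higher of 26 (median -0.45, 3.28e-07). With an estimated correlation these 5 lists had adjusted p-values of 0.235, 0.148, 0.226, 0.183 and 0.0796, and by fry 0.0114, 0.000945, 0.0103, 0.00468 and 0.000195. The neuron marker scores of oxaliplatin 4 (0.06) and paclitaxel 4 (0.04) overlapped, beside -0.24 to -0.15 in the other oxaliplatin and 0.21 to 0.39 in the other paclitaxel libraries. The neurofilament gene Nefh was lower (-0.93 ± 0.19, adjusted p = 0.0108, edgeR), as was the small heat shock protein gene Hspb1 (-0.70 ± 0.14, adjusted p = 0.0116), and the clock gene Per2 was higher (1.01 ± 0.17, adjusted p = 0.00537, reads shared in 12 libraries).

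Of the cell type lists, those of red cells, B and plasma cells and fat had the largest medians between the drugs. Of 17 erythroid markers 14 were called higher with oxaliplatin and 1 lower (median 2.32, camera adjusted p = 7.81e-10), among them the hemoglobin gene Hba2 (2.41 ± 0.39), with shared reads. Of 13 markers of B and plasma cells 9 were higher (median 2.51, adjusted p = 1.75e-06), among them Rag1 (2.54 ± 0.46). Adipocyte markers had 8 of 13 called higher (median 1.84, adjusted p = 7.7e-06). With an estimated correlation the adjusted p-values were 0.183, 0.226 and 0.183. Of the 47 lists 34 were called by camera, 2 of them with an estimated correlation, the cell cycle and non-peptidergic nociceptor lists, and 29 by fry.

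Mki67, Alox15, Cd68, Cdkn1a, Gal, Atf3 and Ecel1 kept their calls between the drugs whichever library was left out, and each such fit kept between 83 and 136 of the 137 named genes called. The count of 1788 genes became 3463 without paclitaxel 4, 810, 679 and 601 without paclitaxel 1, 2 and 3, and 901 and 571 without oxaliplatin 2 and 3. It was 1016 with the 2 groups alone and 2 with the erythroid score as a covariate, under which Ptprc and Cd79a had negative log2 fold changes. Myelinating Schwann cells (median 0.31) were not called without oxaliplatin 2 (adjusted p = 0.246), nor oxidative phosphorylation (-0.10) and the interferon response (0.29) without oxaliplatin 4 (0.0665 and 0.0838). The split was 1075 higher and 1167 lower after correction for gene length and 1338 and 1444 with DESeq2. Limma called 1453 higher and 276 lower on log2(FPKM + 1) and 1434 and 273 on log2(FPKM + 0.1).

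Another 3 lists were called between the drugs alone. Voltage-gated sodium channels (median -0.21, camera adjusted p = 0.00299) and markers of peptidergic nociceptors (-0.18, 0.00534) were lower with oxaliplatin than with paclitaxel, and markers of skeletal muscle higher (0.46, 0.0203), with adjusted p = 0.266, 0.183 and 0.318 with an estimated correlation. Neuronal markers were lower beside them (median -0.38, 16 of 16 members), and erythroid (2.32), fibroblast (0.77) and macrophage (0.66) markers higher. Skeletal muscle was not called without paclitaxel 4 or oxaliplatin 4 (adjusted p = 0.0521 and 0.0985). Scn1a (-0.51 ± 0.13) and Scn4b (-0.47 ± 0.12) were the sodium channel members with the smallest p called lower (adjusted p = 0.0235 and 0.0286, edgeR), Scn1a with shared reads. The sodium channel score of oxaliplatin 4 (0.13) lay within the range of the paclitaxel libraries (0.03 to 0.23), beside -0.21 to -0.12 in the other oxaliplatin libraries. Camera called 9 lists in no comparison, with adjusted p-values between 0.0719 and 0.972. Their medians after paclitaxel and oxaliplatin against vehicle were 0.05 and -0.08 for sensory transduction channels, 0.04 and 0.02 for nucleotide excision repair, -0.08 and -0.02 for antioxidant and NRF2 targets, -0.07 and -0.01 for endoplasmic reticulum stress, and -0.15 and -0.22 for the glucocorticoid response. They were -0.12 and 0.02 for drug transport and platinum handling, 0.09 and -0.02 for Schwann repair markers, -0.29 and -0.15 for markers of T and NK cells, and -0.18 and -0.05 for spinal cord markers. The median, mean and test differed in sign for the interferon and clock lists after paclitaxel, the antioxidant and endoplasmic reticulum stress lists after oxaliplatin, and the antioxidant list between the drugs, none of them called there.

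**Figure D3:**
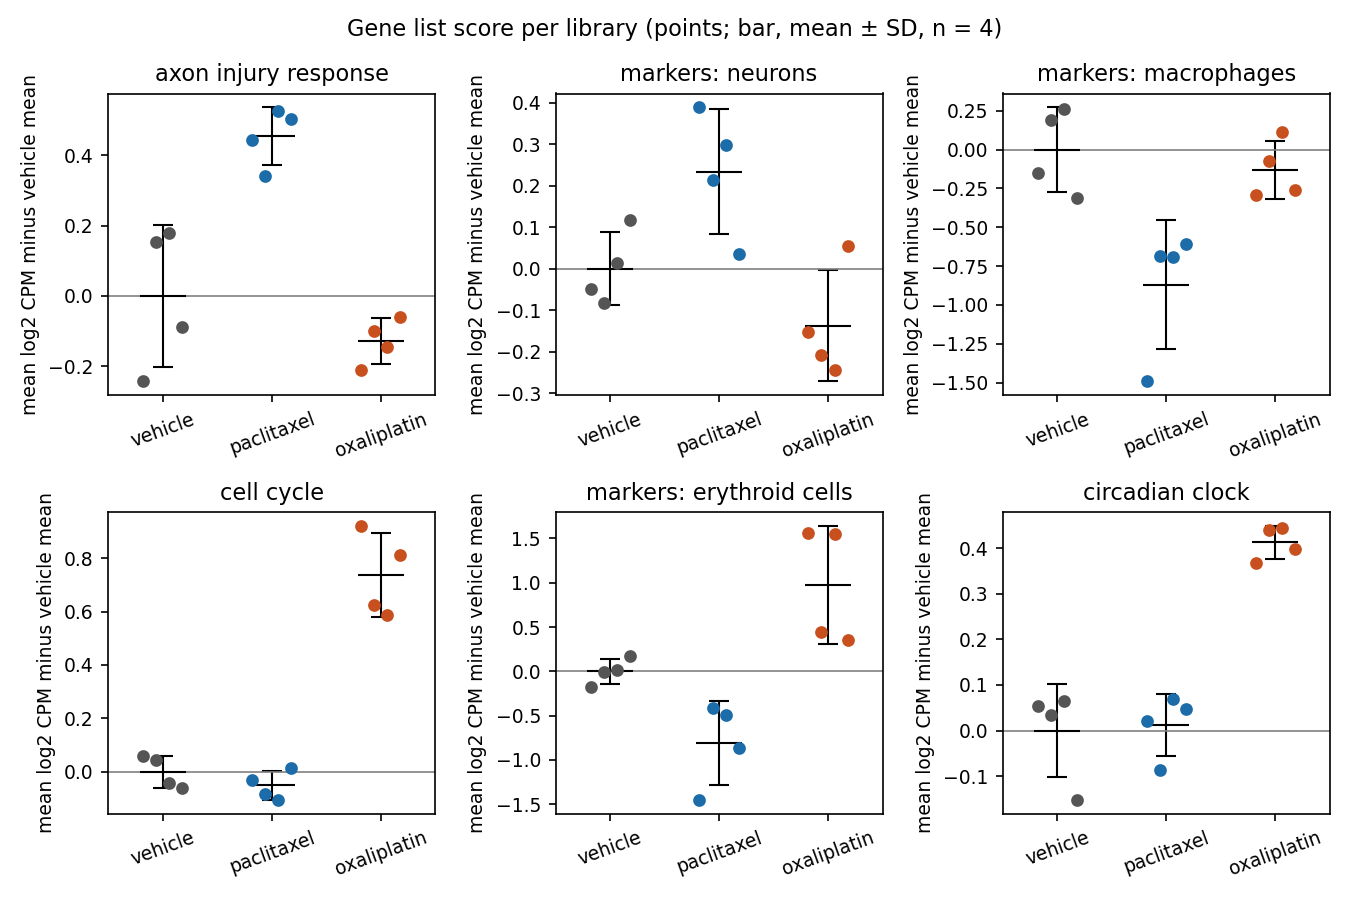
Score of 6 gene lists in each library (points), the mean log2 CPM of the members minus the mean of the vehicle libraries, with the mean ± SD of 4 libraries (bars). The macrophage score of paclitaxel 1 was -1.49 and those of the other paclitaxel libraries lay between -0.69 and -0.61, and the cell cycle score lay between 0.59 and 0.92 in the oxaliplatin libraries.

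The effects of the drugs against vehicle were compared across genes, which are not independent replicates and share the vehicle libraries. The correlation of log2 fold changes over 15809 genes was 0.236, beside a mean of 0.506 (range 0.442 to 0.608) in 20 simulations of unchanged groups. There all libraries, vehicle included, were drawn around the vehicle means with dispersions estimated over the 3 groups. The covariance was 0.031 where the simulations gave 0.0491, a difference of -0.0182. Real vehicle libraries had a chi-square per gene of 11.1 to 22.3 among themselves, beside 8.07 to 44.9 for paclitaxel and 18.5 to 32.7 for oxaliplatin. The simulated covariance may thus be too large, and the difference cannot be read as one between the drugs. With 2 vehicle libraries for each drug the correlation lay between -0.052 and 0.075 over 6 divisions. Ecel1 and Fam150b were among the 3 genes called in both comparisons, all higher, where unchanged groups gave 0.05 genes on average and independent lists 0.137 higher and 0.043 lower.

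Genes chosen in advance for their part in pain included several that did not differ from vehicle by the test. Calca, which encodes the neuropeptide CGRP, had 1284 ± 107 CPM with vehicle, 1756 ± 224 with paclitaxel (0.45 ± 0.11, adjusted p = 0.17, edgeR) and 1344 ± 135 with oxaliplatin (0.07 ± 0.11, adjusted p = 0.808), and was lower with oxaliplatin than with paclitaxel (-0.39 ± 0.11, adjusted p = 0.0362). Trpv1, the capsaicin receptor, had log2 fold changes of -0.01 ± 0.11 and -0.06 ± 0.11 against vehicle after paclitaxel and oxaliplatin, Trpa1, an irritant receptor, 0.09 ± 0.14 and -0.21 ± 0.14, and the sodium channel genes Scn9a -0.06 ± 0.12 and -0.27 ± 0.12 and Scn10a 0.20 ± 0.12 and -0.01 ± 0.12. Ccl2, a monocyte chemokine, had -0.29 ± 0.21 and -0.52 ± 0.21. None of these values passed, with adjusted p-values between 0.227 and 0.972. Cdkn1a had 1.03 ± 0.20 after paclitaxel (adjusted p = 0.0848), and after oxaliplatin Gal had -0.35 ± 0.23 (adjusted p = 0.477) and Atf3 0.15 ± 0.15 (adjusted p = 0.677). Calca, Scn9a and Scn10a are uncertain, with counts that were not whole in 12 libraries.

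**Figure D4:**
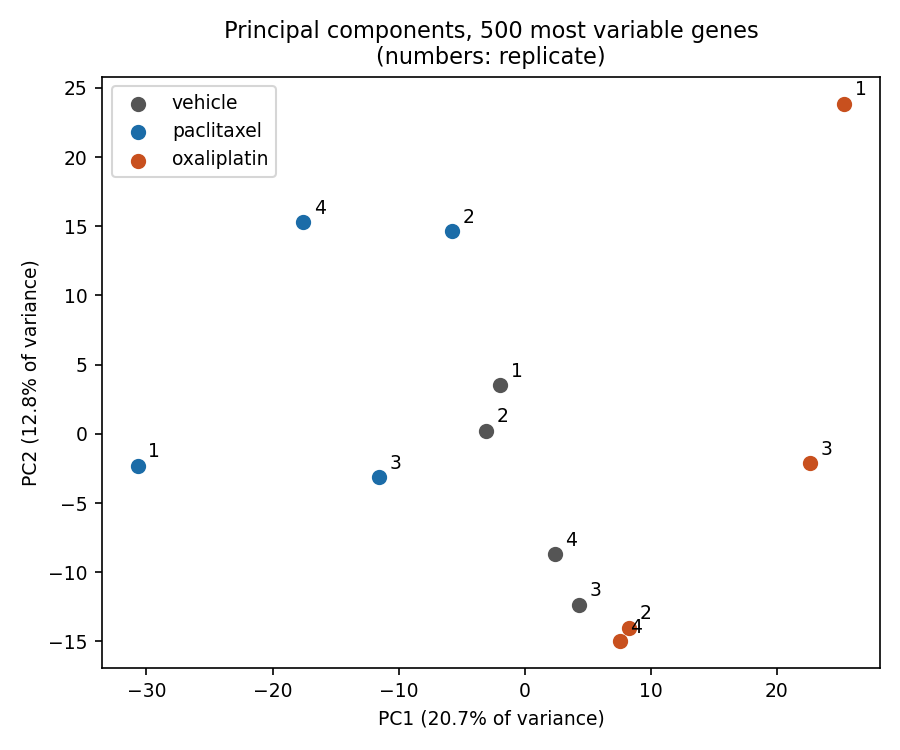
First 2 principal components of log2 CPM over the 500 most variable genes, with 20.7% and 12.8% of the variance on the horizontal and vertical axes, 1 point per library with its replicate number. On the horizontal axis the paclitaxel libraries lay between -30.7 and -5.75, the vehicle libraries between -3.04 and 4.32 and the oxaliplatin libraries between 7.53 and 25.4. On the first component over all 15809 tested genes, not drawn, oxaliplatin 4 (-7.18) lay within the vehicle range (-10.4 to 5.4) and paclitaxel 4 (7.07) close to it.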

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

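The weighing of a larger neuronal share for the macrophage markers and all tests of paclitaxel 4 were chosen after the results were seen, the latter in place of circadian clock genes, for which no such test was run; for the remaining tests, scores per library had been seen before the refits.

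Macrophage markers were lower after paclitaxel (median log2 fold change -0.84, 22 of 22 members, n = 4 libraries per group), and 22 of them had over 1 CPM in vehicle ganglia. A larger neuronal share of the RNA would lower all other cell types alike, but the macrophage score minus the mean of the satellite glial, myelinating Schwann, endothelial and mural scores was -0.697 in paclitaxel relative to vehicle (SD 0.393 and 0.26, exact permutation p = 0.0286 over 70 divisions, the smallest possible), which argues against that share as the whole cause. That p is not independent support, since the contrast was chosen from the same libraries after the results were seen. Fibroblast, neutrophil, erythroid, B-cell, and bone and cartilage lists fell as well and were left out of it. Gene length bias is argued against by a median of -0.784 after correction, with 20 members still lower adjusted over the list alone. Less blood or marrow in the samples stays open: with the erythroid score as a covariate the median was -0.63 with 22 of 22 members lower and a camera adjusted p of 1.13e-10, but the median standard error was 0.277 in place of 0.225, 4 members in place of 20 passed over the list alone, fry gave 0.383, and the score itself did not overlap between the groups. An effect of paclitaxel on resident macrophages is a hypothesis for which no test was run.

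Cell cycle genes were higher after oxaliplatin (median 0.80, 40 of 40 members), and 40 of them had over 1 CPM in vehicle ganglia. Marrow or blood cells that vary with the erythroid score are argued against as the whole cause by a median of 0.779 with that score as a covariate. Under it 38 of 40 members were higher (camera adjusted p = 3.47e-25, fry 0.00144). However, the score did not overlap between the groups. Calls over all genes went from 20 to 6 as the median standard error rose from 0.183 to 0.248. Markers of B and plasma cells and of adipocytes were higher as well, and their scores were not used as covariates, so such cells are not excluded. The cell cycle scores of oxaliplatin 2 and 4 were 0.62 and 0.81 at erythroid scores of 0.45 and 0.36, and those of oxaliplatin 1 and 3 were 0.92 and 0.59 at 1.56 and 1.55. Gene length bias is argued against by a median of 0.801 after correction. A response of dividing cells of the ganglion to oxaliplatin is a hypothesis for which no test was run. The pattern was found, and the other explanations weighed, on the same libraries.

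Paclitaxel 4 stood apart: without it 1631 genes were called in place of 19, and the division that put it with vehicle 1, 2 and 3 gave 27 genes. An exchange of its label with oxaliplatin 4 would fit the largest count of any division between the drugs, 2598 genes, but the cell cycle score of oxaliplatin 4 was 0.812 where no paclitaxel library exceeded 0.012 (SD 0.053), and the axon injury score of paclitaxel 4 was 0.504 where no oxaliplatin library exceeded -0.06 (SD 0.064). A vehicle library under that label is argued against by the same 0.504, beside at most 0.179 in vehicle (SD 0.202), and an equal loss of all neuron classes by the mean nociceptor score minus the neuron marker score, 0.299 above the mean of the other 3 paclitaxel libraries (SD 0.095). A lower neuronal share that spares nociceptors stays open: its neuron marker score was -0.265 against the mean of those 3, with 0.035 beside 0.214 to 0.39, while its peptidergic and non-peptidergic nociceptor scores were 0.11 and 0.08 beside 0.07 to 0.13 and -0.02 to 0.07. Its large myelinated neuron score was -0.22, beside 0.08 to 0.26 in those 3 and -0.14 to 0.05 in vehicle. Of 15 non-neuronal lists 9 were higher in it, 6 of them above the highest of those 3 by over 1 SD. Satellite glia lay 7.45 SD and Schwann repair markers 6.82 SD above their mean. The other 6 lists were lower, against such a share, but 0 lay below the lowest of those 3 by over 1 SD. Skeletal muscle was lower by -1.24 SD, and the other 5 (erythroid, neutrophil, B and plasma cell, adipocyte, and bone and cartilage) were within 1 SD. That is too little in 1 library to exclude it, and no biological explanation was tested.

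Each count was set beside the 35 ways to divide its 8 libraries into 4 and 4. For paclitaxel against vehicle 2 divisions gave as many genes (real 19, highest other 27) and 7 as many lists (21 and 30), so chance cannot be excluded for either count. For oxaliplatin against vehicle 1 division, the real one, gave as many genes (278, highest other 1). That argues against chance for that count, though 1 of 35 is the smallest share possible and several counts were examined. In the same comparison 6 divisions gave as many lists (24 and 27), so chance cannot be excluded there. Such divisions cannot tell a drug effect from another difference between the groups. Between the drugs 2 divisions gave as many genes (1788 and 2598), so chance is not excluded, and the larger count came from the division that exchanges paclitaxel 4 and oxaliplatin 4. For lists between the drugs, 1 division, the real one, gave as many (34, highest other 33). Chance is argued against there only by a margin of 1 list, where leaving out 1 library moved the count between 33 and 36.

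Of 432 sets of 4 libraries examined for 105 genes, 38 list scores and the total count per library, 25 held a library far from the other 3 by Dixon's criterion, where chance gives about 1 in 20. In paclitaxel 1 the macrophage score was -1.492 beside -0.694 to -0.608 in the other paclitaxel libraries, the complement score -0.769 beside -0.28 to -0.252 and the Toll-like receptor score -0.612 beside -0.283 to -0.225. In that library Itgam was at 1.451 CPM, Sfrp4 at 6.108, P2rx3 at 765.6 and Hspb1 at 333.4. Spi1 was at 7.451 CPM and the bone and cartilage score at -0.294 in paclitaxel 2, and Rpl7 at 351.6 CPM and the synaptic vesicle score at -0.036 in paclitaxel 4. In oxaliplatin 4 Alox15 was at 70.5 CPM beside 142.6 to 148.6, Dbp at 47.19, Tifab at 4.663 and Scn1a at 109.7. In oxaliplatin 3 Per3 was at 55.35 CPM, Per2 at 23.72 and Srxn1 at 82.8. Among vehicle libraries Stmn4 was at 19.99 CPM in vehicle 1, Ifi27l2b at 155.4 and the large myelinated neuron score at -0.136 in vehicle 2, Uqcrfs1 at 100.9 and Cidec at 1.431 CPM in vehicle 3, and Dnajb4 at 65.83 CPM and the clock score at -0.152 in vehicle 4.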

How the results depend on the processing

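The erythroid covariate, the length correction and the fit without genes that share reads were chosen after the data were seen, and for each difference below the cause was not tested unless named. In order paclitaxel against vehicle, oxaliplatin against vehicle and oxaliplatin against paclitaxel, the 19, 278 and 1788 genes became 238, 904 and 2782 with DESeq2, 2271, 631 and 4796 with limma voom, and 7, 21 and 2 with the erythroid covariate, a score that did not overlap between the groups. Oxaliplatin against vehicle gave 161 genes and the drugs 1016 with only the 2 groups compared, 71 and 337 at a fold of at least 2, which removes genes by construction, and the former 418 after length correction. Leaving out 1 library at a time gave 10 to 1631, 49 to 242 and 571 to 3463 genes, and 20 to 24, 22 to 27 and 33 to 36 lists. Of the named genes called, 4 to 10 of 10, 28 to 50 of 63 and 83 to 136 of 137 kept their call in those fits, and 3, 15 and 2 with the erythroid covariate. Macrophage, axon injury and neuron lists after paclitaxel, and cell cycle, p53 and clock lists after oxaliplatin, kept their camera call in every fit without 1 library. With an estimated correlation 0, 3 and 2 lists were called, and by fry 3 and 8 against vehicle.

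With the replicate number as a block, 72 genes were called after oxaliplatin and 986 between the drugs, and 15 after paclitaxel. To look for pairing, the deviations of each library from its group means were correlated across genes. These correlations lay between -0.232 and 0.157 for libraries with the same number. The deviations of 0 libraries for paclitaxel against vehicle, 2 for oxaliplatin against vehicle and 0 between the drugs correlated best with those of their own number. This gave no clear sign of pairing, but weak correlations cannot exclude that equal numbers mark a shared batch.

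The erythroid covariate reversed the values of Ptprc (-0.34), Pax5 (-0.0621), Fcrla (-0.0083), Cd79a (-0.21), B and plasma cells (-0.21), neutrophils (-1.40) and MHC class II (-0.57) between the drugs, of B and plasma cells (0.26) after paclitaxel, and of B and plasma cells after oxaliplatin (-0.063). The erythroid list's own score is the covariate, so its difference is adjusted away by construction and its remaining sign tells nothing. Its median was 0.0786 after paclitaxel, and between the drugs camera's direction turned at a median of 0.22. The ribosomal list, not called after oxaliplatin, was called higher without vehicle 2 (median 0.125, adjusted p = 0.0116), without oxaliplatin 4 (0.0991, 0.00388) and after length correction (0.0687, 0.0128), and its median lay between -0.09 and 0.125 without 1 library.

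The correlation of 0.236 between the drug effects became 0.4 with DESeq2, 0.41 with no filter and 0.137 with a strict one, and 0.184 to 0.382 without 1 library. With 2 vehicle libraries for each drug it was 0.025, -0.052, 0.066, -0.047, 0.075 and -0.044. Genes called with both drugs numbered 24 with DESeq2, 66 with limma voom, 2 to 42 without 1 library, and 1, 2, 0, 1, 0 and 1 with 2 vehicle libraries for each drug. The first component held 24.6% of the variance over all tested genes in place of 20.7%. In the simulation 76.8% of 2-fold changes were called for the paclitaxel comparison, so changes of that size and smaller can be missed. Each gene was drawn independently there, so that share need not hold for the real libraries. Among these, some differences over 2-fold did not pass after paclitaxel, such as those of Ctsg, Sfrp4, Tlr7 and Cdkn1a given above. Whether those were true changes that the test missed cannot be told from these libraries. In the simulation 97.9% of 4-fold changes were called for the paclitaxel comparison, so larger changes can be missed as well.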

Other observations

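The genes named in this part were chosen after their values were seen, within the lists fixed before the data were examined.

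Some stress and immune genes rose after oxaliplatin in lists that camera did not call, beside the higher erythroid, B-cell and adipocyte markers of that comparison (n = 4 libraries per group). Ddit3, the transcription factor CHOP, rose 1.78-fold (log2 fold change 0.84 ± 0.15, adjusted p = 0.0186, edgeR), C4a, a complement component, 2.14-fold (1.10 ± 0.21, adjusted p = 0.0229) and Mt2A, a metallothionein that binds metal ions, 2.00-fold (1.00 ± 0.24, adjusted p = 0.049), with reads shared in 12, 12 and 8 libraries. Pold1, the catalytic subunit of DNA polymerase delta, rose 1.49-fold (0.57 ± 0.13, adjusted p = 0.0413) and Irak3, an inhibitor of Toll-like receptor signalling, 1.56-fold (0.64 ± 0.15, adjusted p = 0.0463). Tsc22d3, a glucocorticoid-induced leucine zipper protein, fell from 259 ± 20.2 to 183 ± 14.6 CPM (-0.50 ± 0.08, adjusted p = 0.0117), as did Il7r, a cytokine receptor subunit (-0.57 ± 0.12, adjusted p = 0.0293), and Hapln1, a matrix link protein (-0.66 ± 0.13, adjusted p = 0.0228).

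Between the drugs, Igf1 (log2 fold change 0.97 ± 0.18, adjusted p = 0.00897, edgeR) was higher with oxaliplatin and Bdnf, a neurotrophin, lower (-0.76 ± 0.18, adjusted p = 0.0221), beside 24.1 ± 2.36 CPM with paclitaxel, 15.5 ± 3.59 with vehicle and 14.3 ± 3.65 with oxaliplatin. Npy2r, a neuropeptide Y receptor, was lower with oxaliplatin (-0.98 ± 0.19, adjusted p = 0.00975), and P2rx7, an ATP-gated channel of immune cells and glia, higher (0.86 ± 0.20, adjusted p = 0.0185).

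The circadian clock score was 0.37, 0.44, 0.45 and 0.40 in oxaliplatin 1 to 4, between -0.09 and 0.07 in the paclitaxel libraries and between -0.15 and 0.07 in the vehicle libraries. The hour at which tissue was taken is not in the labels, and no explanation was tested.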
